A study of Brassica napus and Brassica oleracea and Brassica rapa with 24 samples.

How the data were processed

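Leaves of 4 Brassica genotypes were sampled 24 hours after inoculation with Sclerotinia sclerotiorum or a mock plug. Per the labels, the plants were 3 weeks old and grown at 20 °C, the plugs were 7 mm wide and the inoculated leaves stood in a chamber at 18 °C. The deposited files hold counts: the authors counted fragments per gene, summed over the exon intervals listed for the gene, with no normalization. Per the file headers, featureCounts 1.5.2 was run on fragments, without the strand option and without counting multi-mapping reads, on a separate gene set for each genotype. Per the labels, reads were trimmed with Trimmomatic 0.32 and aligned with STAR 2.7, and edgeR 3.20.9 was named for the tests. The resynthesized line was counted on the joined B. rapa and B. oleracea gene sets, so its A genes share identifiers with B. rapa and its C genes with B. oleracea. Natural B. napus has a second count per library, on a pan-genome gene set, used as an alternative. For 1 library, mock replicate 1 of B. oleracea, the column name says that several read files were joined.

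Groups followed the labels. For 1 library of resynthesized B. napus the treatment label says mock while the code in its title reads as infected, so it is in no group and both readings were run as alternatives. For another library of that line, title and code gave different replicate numbers but the same treatment. Intervals and floors cover counting error only, since reads without molecular identifiers are not independent molecules.

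Each genotype was tested alone with the edgeR 4.0.16 quasi-likelihood F test (trimmed mean scaling, filterByExpr, infected against mock), in R 4.3.3, and genes with a Benjamini-Hochberg adjusted p under 0.05 were called. Responses of resynthesized B. napus and each progenitor were compared by the interaction of genotype and treatment on shared identifiers. Shares of subgenome counts were compared with an exact two-sided permutation test of library values, and called shares and overlaps with Fisher's exact test, two-sided. The A to C ratio of homeolog pairs was tested with limma 3.58.1 (moderated, with a trend) on the log2 ratio of counts within each library, with 0.5 added to each count, for pairs with at least 10 counts (A and C together) in every library. Levels of the copies were divided by gene length. DESeq2 1.42.0 was run as an alternative. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9. Log2 fold changes were correlated across genes in 4 comparisons with natural B. napus, 2 with the progenitors and 2 between homeologs, without a p.

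The tests were tried on simulated data with the dispersion of the real libraries. Of genes simulated with a 4-fold change, 93.8% were called in natural B. napus, 70% in resynthesized B. napus, 96.9% in B. rapa and 96.9% in B. oleracea, and of 2-fold changes 22.2%, 29.6%, 48.5% and 37.5%. For the interaction of B. rapa and the A genes, 70.4% of 4-fold and 5.05% of 2-fold differences were called. For the homeolog ratio, 75% and 43% of 4-fold changes and 11.2% and 0% of 2-fold changes were called in natural and resynthesized B. napus. Calls among genes simulated without a change numbered 2 to 8 per test. Only 96 to 100 genes or pairs were changed at each fold size, of 7196 to 59885 per test. That is a far smaller share than was called in the real data. Recovered shares and false calls depend on the share of changed genes, so these values do not carry over to the real tests.

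No names or sequences paired the A and C copies, so pairs were built from exon structure and gene order, a departure from the planned sources that was chosen after the data were seen. A pair had at least 3 exons in each gene and an exon length similarity of at least 0.6, with at least 3 other candidate pairs within 20 genes on both chromosomes, and each gene was the best match of the other. This gave 8462 pairs in natural B. napus and 13672 between B. rapa and B. oleracea, against 4 and 5 with shuffled structures. Natural A genes were matched to B. rapa in 10515 cases and natural C genes to B. oleracea in 12284.

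Segments of altered level were also sought after the data were seen. For each library of resynthesized B. napus, CPM (counts scaled to the same total) within a subgenome were divided by the mean of the progenitor libraries of the same treatment, with 0.1 added, for genes with at least 3 CPM in the progenitor. Medians over windows of 25 genes were taken, and runs of at least 3 windows below -1.5 in at least 1 library, or above 0.8 in all, formed a segment. Losses placed in progenitor libraries were found in 30 of 30 trials in each progenitor, with 0 false segments. The placed losses were deeper than the threshold and longer than 3 windows, and each library was compared with others of its own genotype. The trials therefore do not show how well shallower segments are found, or how many false segments a comparison between genotypes gives.

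Of 101040 natural identifiers, 3347 matched the reference table of names and 2 of these carried another name. Of 106836 B. rapa and B. oleracea identifiers, 0 matched. The gene lists planned before the data were examined could therefore not be tested. The rule for named genes, set at the same time, then allowed at most 2 identifiers that rose and 2 that fell per genotype. They are those with the highest and lowest log2 fold changes among called genes with a mean of at least 10 CPM and every infected library beyond every mock library. Of tested genes, 70.9% to 79.2% had groups that do not overlap, where random order gives 10% for 3 against 3 libraries and 20% for 2 against 3. The 2 genes with another name stand outside that rule and were chosen after their values were seen.

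Alternatives set before the data were examined were other scalings (size factors, total counts), DESeq2, no low count filter, a mean of at least 50 counts, a fold threshold, each library left out, a replicate block, the pan-genome counts, both readings of the conflicting labels, other count minimums and pseudocounts for the ratio, counts per kb, genes matched on mean counts in 5 bins, and each subgenome normalized on its own. Chosen after the data were seen were leaving out the altered segments and their homeologs, a fold threshold for the ratio, and other settings of the segment scan. Where a left-out library leaves 1 infected library in resynthesized B. napus, that library is assumed to vary like the other groups. Splicing and fungal transcripts were not analysed here.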

Results

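The data are gene counts from 24 RNA libraries of Brassica leaves, taken 24 hours after a 7 mm plug of Sclerotinia sclerotiorum mycelium (infected) or a mock plug was placed on the leaf. Sclerotinia sclerotiorum is a fungus that kills plant tissue and feeds on it. There were 4 genotypes: natural B. napus, resynthesized B. napus, and the progenitor species B. rapa and B. oleracea. B. napus carries an A subgenome, related to B. rapa, and a C subgenome, related to B. oleracea, and the corresponding A and C copies of a gene are called homeologs. Each group held 3 libraries, except that the infected group of resynthesized B. napus held 2, because the labels of 1 library gave both treatments and it was placed in no group. Totals per library were 60264581 to 83408112 counts in infected and 90301339 to 168500731 in mock leaves of natural B. napus, and 79306667 to 83738831 and 100484486 to 110287195 in resynthesized B. napus. They were 50586484 to 67515744 and 51495342 to 56030548 in B. rapa, and 39789432 to 60829966 and 46530901 to 82816631 in B. oleracea. Levels are in CPM, counts scaled to the same total in every library. Positions are those listed with the counts, whose genome builds are not given in the sources used here. No list of gene functions could be joined to the gene identifiers, so genes appear by identifier and position. Splicing, which the series title also names, was not analysed here.

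Infection changed most measured genes of natural B. napus leaves. Of 60559 genes tested, 19399 rose and 20155 fell (edgeR, adjusted p under 0.05, 3 infected and 3 mock libraries), and 13479 of the risen and 15624 of the fallen genes changed at least 2-fold. BnaC06g27680D, on C06 from 29089158 to 29090481, rose from 0.0277 ± 0.034 to 111.0 ± 63 CPM (SD, n = 3 per group), a log2 fold change of 12.24 with SE 0.79 (11.57 to 13.59 with a library left out). BnaA01g18100D, on A01 from 9569676 to 9571214, rose from 0.124 ± 0.15 to 121.0 ± 3.7 CPM, a log2 fold change of 9.88 with SE 0.89 (9.37 to 11.53 with a library left out). BnaAnng02960D, on an unplaced A sequence, fell from 28.5 ± 4.7 to 0.0682 ± 0.058 CPM. BnaA06g38230D, on an unplaced part of A06, fell from 43.1 ± 17 to 0.104 ± 0.06 CPM. Only 2 of the matched identifiers carry another name. BnaA02g32290D, named KCP1, fell from 46.9 ± 3.6 to 10.9 ± 1.8 CPM, and BnaCnng15100D, named TR1, rose from 17.9 ± 1.5 to 57.8 ± 5.5. Their adjusted p values from edgeR were 8.93e-05 and 0.000129.

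Many tested genes of resynthesized B. napus also changed. Of 58768 genes tested, 17041 rose and 19718 fell (edgeR, 2 infected and 3 mock libraries), 11365 and 15445 of them at least 2-fold. Without infected replicate 1 or 3, 29301 of 60610 and 26251 of 60659 tested genes were called. BraA05g003290.3C, on A05 from 1751826 to 1753394, had 0 counts in every mock library and 30.4 ± 1.5 CPM in infected leaves (SD, n = 2), at least 1020-fold higher against a floor of 3 counts per library. In B. rapa the same gene rose by 6.33 on the log2 scale with SE 1.14. BraA09g025850.3C, on A09, held 2 counts over the mock libraries and 18217 over the infected ones, a ratio of 17400 in CPM with a 95% exact counting interval of 4820 to 144000. BraA01g006370.3C, on A01, held 6419 mock and 3 infected counts, a ratio of 1120 with an interval of 382 to 5420, and it also fell in B. rapa, with a log2 fold change of -6.33. BraA02g022450.3C, on A02, fell from 27.2 ± 2.3 to 0.0242 ± 0.016 CPM. In B. rapa its log2 fold change was -0.73 with SE 1.19 and did not pass the test. Interaction values of single genes are not given here, so no difference between the genotypes is claimed for this gene. With the library of conflicting labels counted as infected, 40233 genes were called. With it counted as mock, edgeR called 0 genes, 10116 had an unadjusted p under 0.05, and DESeq2 called 4718. Across genes, which are not independent replicates, that library had an r of 0.995 and 0.996 with the infected and 0.86 to 0.865 with the mock libraries of its line.

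In B. rapa 8289 genes rose and 8208 fell of 27382 tested (edgeR, 3 infected and 3 mock libraries), and 4993 and 4423 of these changed at least 2-fold. The 2 fallen genes that the naming rule picked were abundant in mock leaves. BraA02g037860.3C, on A02 from 26487364 to 26488247, fell from 3520 ± 580 to 12.3 ± 6.5 CPM (SD, n = 3), and BraA09g003290.3C, on A09, fell from 2990 ± 470 to 10.9 ± 7.2. Both also fell in resynthesized B. napus, by -6.89 and -7.14 on the log2 scale. BraA05g013310.3C, on A05, held 2 mock and 4489 infected counts, a ratio of 2070 with a counting interval of 572 to 17100. BraA04g028260.3C, on A04, held 2 mock and 3489 infected counts, a ratio of 1610 with an interval of 445 to 13300. The first of these rose in resynthesized B. napus by 9.07 on the log2 scale, and the second held 3 mock and 1727 infected counts.

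In B. oleracea 10099 genes rose and 10839 fell of 29862 tested (edgeR, 3 infected and 3 mock libraries), 6321 and 7878 of them at least 2-fold. Bo8g105180.1, on C08 from 36981955 to 36985097, had 0 counts in every mock library and 20.5 ± 9.2 CPM in infected leaves (SD, n = 3), at least 318-fold higher. It also rose in resynthesized B. napus, by 7.78 on the log2 scale, and its matched gene in natural B. napus, BnaC08g38040D, rose by 5.46. Bo4g031180.1, on C04, held 2 mock and 18006 infected counts, a ratio of 10700 with a counting interval of 2970 to 88700, and it rose by 9.02 on the log2 scale in resynthesized B. napus. Bo9g163570.1 fell from 48.3 ± 6.9 to 0.112 ± 0.074 CPM and Bo9g022280.1 from 1260 ± 210 to 6.87 ± 9.1, both on C09. The infected libraries held 0.352 to 17.3 CPM of the second, whose log2 fold change of -7.16 ran from -9.07 to -6.6 with a library left out. The C09 genes also fell in resynthesized B. napus, by -4.97 and -6.49 on the log2 scale.

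**Figure D1:**
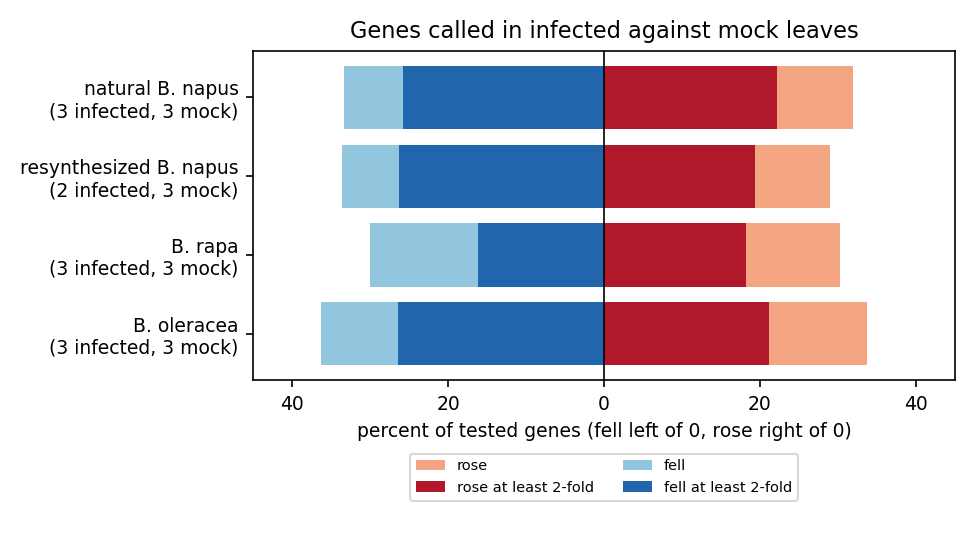
Percent of tested genes called as risen (right of 0) and fallen (left of 0) in infected against mock leaves, for each of the 4 genotypes; the darker part of each bar holds genes that changed at least 2-fold. The 2-fold part of the fallen genes is smallest in B. rapa, with 4423 genes.

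The balance of risen and fallen genes depended on the scaling. With trimmed mean scaling, risen genes made up 49% of called genes in natural B. napus, 46.4% in resynthesized B. napus, 50.2% in B. rapa and 48.2% in B. oleracea. Scaling by total counts alone shifted the median log2 fold change by -0.141, -0.278, -0.254 and -0.426 in that order, and the shares became 43.9%, 35.3%, 36.2% and 32.4%. The typical size of a change, the median absolute log2 fold change, was 1.03 in natural B. napus, 1 in resynthesized B. napus, 0.672 in B. rapa and 0.984 in B. oleracea.

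The most abundant transcripts of mock leaves held a smaller share of the counts after infection, and B. rapa kept more of that share than the other genotypes. The 100 genes with the highest counts in mock replicate 1 held 15.7% ± 0.021 of all counts in the other mock libraries (SD, n = 2) and 2.21% ± 0.5 in infected libraries (n = 3) of natural B. napus. For resynthesized B. napus the share went from 17.3% ± 0.59 to 3.03% ± 0.47 (n = 2 and 2), and in B. oleracea from 21.3% ± 1.3 to 4.87% ± 2 (n = 2 and 3). In B. rapa it went from 19.1% ± 1.2 to 9.87% ± 1.4 (n = 2 and 3). In every genotype the highest infected library stayed below the lowest mock library. Sets picked for being high in infected replicate 1 ran the other way. Their share went from 3.78% ± 0.42 to 10% ± 0.23 in natural B. napus, from 12.4% ± 0.39 to 18.4% ± 1.2 in B. rapa and from 7.41% ± 0.48 to 17% ± 2.7 in B. oleracea (n = 3 mock and 2 other infected libraries), and from 5.42% ± 0.28 to 12.7% in resynthesized B. napus (n = 3 and 1).

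**Figure D2:**
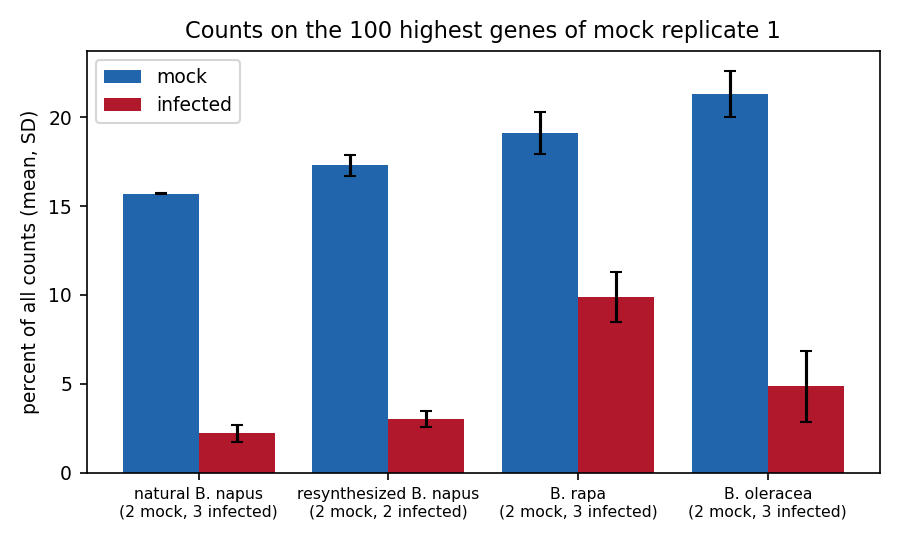
Percent of all counts (mean, with SD as bars) held by the 100 highest genes of mock replicate 1, in the other mock libraries and in the infected libraries of each genotype. The infected mean is 9.87% in B. rapa and between 2.21% and 4.87% in the other genotypes.

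A common set of genes responded in natural B. napus, resynthesized B. napus and a progenitor. Genes of natural B. napus were matched to progenitor genes by exon structure and gene order. Of 7694 matched A genes tested in all 3, 1228 rose in each against 254 expected from independent calls, and 1197 fell in each against 251. Of 8569 matched C genes, 1767 rose in each against 342 expected, and 1690 fell in each against 315. These counts need a call in resynthesized B. napus. There edgeR called 40233 genes with the library of conflicting labels counted as infected and 0 with it counted as mock. Across genes, which are not independent replicates, the log2 fold changes in natural B. napus correlated with those in B. oleracea at r = 0.795 over 8658 genes and with those in B. rapa at r = 0.587 over 8005 genes. With the A genes of resynthesized B. napus r was 0.726 over 7151 genes, and with its C genes 0.738 over 7972. Both values leave out the lower segments of that line, described further on, and their homeologs. The values for the progenitors keep those genes. Shuffled matches gave r between -0.0337 and 0.0302. Of the genes called in both natural B. napus and B. rapa, 82.9% changed in the same direction, against 94.3% for B. oleracea.

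The next comparison asks whether genes respond differently in resynthesized B. napus than in its progenitors. The A genes responded more strongly in resynthesized B. napus than in B. rapa. Of 29642 shared genes, 6040 had a different response (edgeR, interaction of genotype and treatment, adjusted p under 0.05). Of the 5748 that were also tested in each genotype, 3232 had log2 fold changes of the same sign and larger in resynthesized B. napus, 598 of the same sign and larger in B. rapa, and 1918 of opposite sign. Those of opposite sign passed the test in both genotypes in only 361 genes outside and 21 inside the altered segments described further on. Over 25493 genes the standard deviation of the log2 fold changes was 2.18 in resynthesized B. napus and 1.65 in B. rapa, and their r across genes was 0.82. For the medians that follow, matched A genes outside the lower segments and their homeologs were used. Among 257 of them below -3 (log2) in natural B. napus, the median was -3.43 in resynthesized B. napus and -1.45 in B. rapa. Among 323 genes at 3 or more, the medians were 3.54 and 2.71. With the library of conflicting labels counted as infected, 7962 genes had a different response, and with a replicate block 3925 did. The count of 6040 was 3834 without B. rapa mock replicate 2, 2220 without resynthesized infected replicate 3, and 74 with the library of conflicting labels counted as mock.

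**Figure D3:**
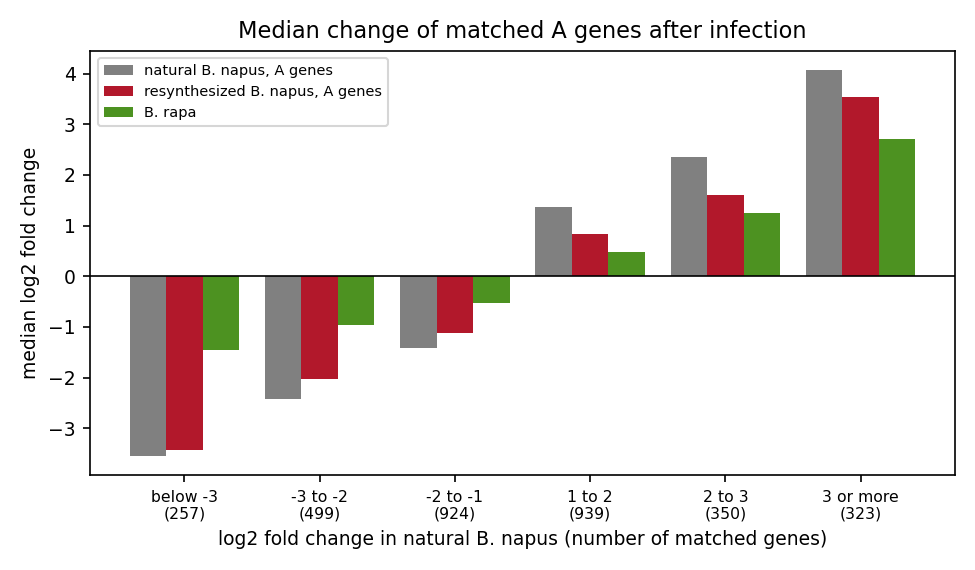
Median log2 fold change (vertical axis) of matched A genes in natural B. napus, resynthesized B. napus and B. rapa, with genes grouped by their log2 fold change in natural B. napus (horizontal axis, number of genes in brackets). Genes in the lower segments of resynthesized B. napus and their homeologs are left out. The B. rapa bar is the shortest in each of the 6 groups.

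The C genes of resynthesized B. napus and B. oleracea differed less. Of 32239 shared genes, 2111 had a different response (edgeR, interaction). Of the 2020 also tested in each genotype, 619 had log2 fold changes of the same sign and larger in resynthesized B. napus, 701 of the same sign and larger in B. oleracea, and 700 of opposite sign. Of the last, 163 outside and 23 inside the altered segments passed the test in both genotypes. Over 28021 genes r across genes was 0.883, with standard deviations of 2.13 and 2.09. The count of 2111 rested on single libraries. It was 422 without resynthesized infected replicate 1, 561 without infected replicate 3 and 1366 without mock replicate 3. It was 1084 and 4390 without B. oleracea infected replicates 1 and 2, and 869, 1026 and 1275 without its mock replicates 1, 2 and 3. It was 4033 or 38 with the library of conflicting labels counted as infected or as mock, and 518 with a replicate block.

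The overlap of calls between resynthesized B. napus and its progenitors was large in both directions. Of 25534 genes tested in both resynthesized B. napus and B. rapa, 5703 rose in both against 2339 expected from independent calls (Fisher's exact test, odds ratio 21.9), and 5623 fell in both against 2582 expected (odds ratio 13.6). Of 28035 genes tested in both resynthesized B. napus and B. oleracea, 7258 rose in both against 2932 expected (odds ratio 40.7), and 7753 fell in both against 3396 expected (odds ratio 32.6). Genes are not independent replicates. Over both progenitors and both directions, the overlap held 26337 genes, and 27890 with the library of conflicting labels counted as infected. With that library counted as mock the overlap was 0, since edgeR then called 0 genes in resynthesized B. napus. A count of overlap at an unadjusted p was not made.

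The series title concerns dominance of 1 subgenome, so the A and C parts of the counts were compared. In natural B. napus the A genes held 49.7% ± 0.15 of the subgenome counts in mock and 49% ± 0.4 in infected leaves (SD, n = 3), a difference of -0.72 points (exact permutation test, two-sided, p = 0.1). In resynthesized B. napus they held 42.6% ± 0.39 in mock (n = 3) and 41.4% ± 0.11 in infected leaves (n = 2), a difference of -1.23 points (exact permutation test, two-sided, p = 0.1). Neither design can give a p below 0.1. Without the 100 genes of highest mean counts the difference was 0.151 points in natural and -2.09 points in resynthesized B. napus. A genes made up 44.2% of the listed A and C genes in natural and 45.8% in resynthesized B. napus. In the resynthesized line the counts include the lower segments described further on, with 6.84% of the A and 4.74% of the C genes.

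A larger share of A genes than of C genes responded in natural B. napus. There, 66.9% of 28757 tested A genes and 64% of 31638 tested C genes were called, a difference of 2.88 points (Fisher's exact test, p = 1.01e-13; genes are not independent replicates). Risen genes made up 33.3% of the A genes and 31% of the C genes (Fisher's exact test, p = 2.63e-09), and fallen genes 33.6% and 33% (p = 0.108). Among the genes tested in the resynthesized line, 62.9% of 27243 A genes and 62.2% of 31525 C genes were called, a difference of 0.662 points that did not pass the test (Fisher's exact test, p = 0.0991). That difference was 1.82 points without the genes in the altered segments described further on (Fisher's exact test, p = 9.89e-06), and -0.669 points when each subgenome was normalized on its own (p = 0.0964). It was 1.21 points for changes of at least 2-fold, 2.47 without a low count filter, 0.947 with genes matched on mean counts, and 0.803 and 1.69 without infected replicate 1 and without mock replicate 2, each with p under the threshold. Leaving out mock replicate 3, mock replicate 1 or infected replicate 3 gave 0.0692, 0.392 and 0.605 points (Fisher's exact test, p = 0.873, 0.339 and 0.135).

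Where both homeologs were called, they mostly moved in the same direction. In natural B. napus, among 6603 pairs with both copies tested, both copies were called in the same direction in 3484 pairs and in opposite directions in 120. These counts were 5000 and 210 of 10657 pairs in resynthesized B. napus. Only 1 copy was called in 1788 and 3070 pairs, and neither in 1211 and 2377. Among pairs with both copies called, 96.7% and 96% had the same direction, against 47.9% to 52.1% for randomly paired copies. Across pairs, which are not independent replicates, the log2 fold changes of the A and C copies correlated at r = 0.85 and 0.84.

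The A to C ratio nevertheless shifted in part of the pairs. In natural B. napus 2384 of 6839 pairs changed ratio (limma, adjusted p under 0.05, 3 infected and 3 mock libraries), 1219 toward A and 1165 toward C, and 1029 of them changed at least 2-fold. In resynthesized B. napus 2477 of 11416 pairs changed (limma, 2 infected and 3 mock libraries), 1020 toward A and 1457 toward C, 1425 of them at least 2-fold. This second count was 597 and 242 without infected replicates 1 and 3, and 1201 and 861 without mock replicates 1 and 3. With a replicate block it was 1618 pairs, 786 toward A and 832 toward C. Counting the library of conflicting labels as infected gave 3602 pairs, 1565 toward A and 2037 toward C. With that library counted as mock, limma called 0 pairs, and 1093 had an unadjusted p under 0.05. The log2 ratios were not centred within libraries. In the resynthesized line their median over tested pairs was -0.583 and -0.565 in the infected libraries. It was -0.481, -0.529 and -0.495 in the mock libraries. The counts toward A and C in that line include this general shift toward C.

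The C copy was more often the higher one, before and after infection. In mock leaves of natural B. napus the A copy was at least 2-fold higher in 940 pairs and the C copy in 1329 (limma, adjusted p under 0.05), and in infected leaves in 1087 and 1449. The counts in resynthesized B. napus were 1480 and 3903 in mock leaves and 1453 and 4087 in infected leaves. Outside the altered segments of that line they were 919 and 3016, and 966 and 3309. Over all tested pairs, the median log2 A to C ratio was -0.117 in mock and -0.115 in infected leaves of natural B. napus. In resynthesized B. napus it was -0.501 and -0.573, and -0.468 and -0.532 outside those segments. The 2-fold counts include this shift of the median pair and were not centred on it. The side that was at least 2-fold higher switched between mock and infected leaves in 13 pairs from A to C and 20 pairs from C to A in natural B. napus, and in 26 and 27 pairs in resynthesized B. napus. Levels of the copies are per coding length in resynthesized B. napus and per annotated exon length in natural B. napus, and reads that map to both copies were not counted.

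**Figure D4:**
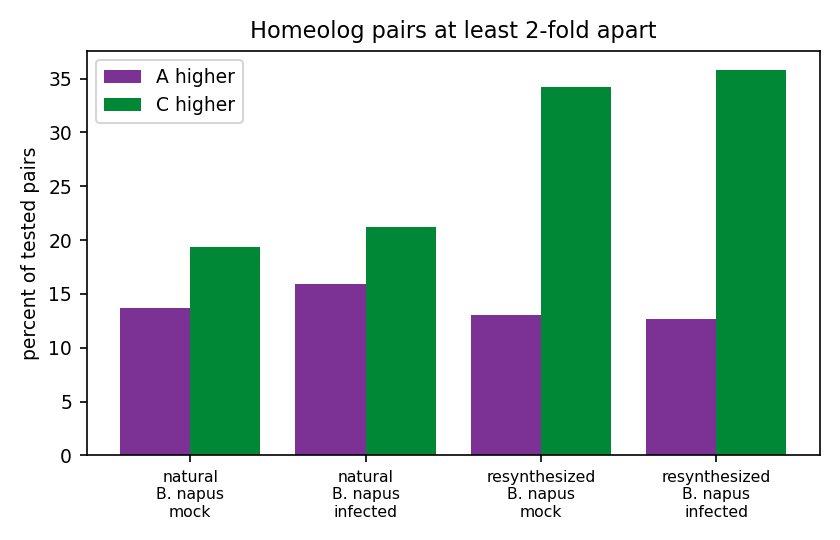
Percent of tested homeolog pairs (vertical axis) in which the A copy or the C copy was at least 2-fold higher, in mock and infected leaves of natural and resynthesized B. napus. The C bar is higher than the A bar in all 4 groups, at 34.2% against 13% in mock leaves of resynthesized B. napus.

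The ratio between homeologs of resynthesized B. napus was also set beside the ratio between the progenitors. Outside the altered segments, the log2 ratio in the line correlated with that between B. rapa and B. oleracea at r = 0.682 across 7741 pairs in mock leaves and 0.709 across 7025 pairs in infected leaves. With all pairs, r was 0.415 and 0.477. For the shares that follow, the median log2 ratio of pairs outside the segments was first subtracted, in the progenitors and in the line. A side counted as higher is therefore higher than in the median pair, unlike the levels of the copies given above. Pairs whose higher side was opposite to that of the progenitors by at least 2-fold on each side made up 0.969% in mock and 1.17% in infected leaves outside the segments. On the same scale, of pairs with the A side at least 2-fold higher in the progenitors, 44.6% in mock and 47.2% in infected leaves kept that difference in the line. With the C side higher, 44.8% and 54.8% did.

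Long segments of resynthesized B. napus were far below the level of the progenitor. The scan took medians over windows of 25 neighbouring genes, as the log2 ratio of each library to the progenitor group of the same treatment, and took runs of 3 or more windows below -1.5 in at least 1 library. It found 2 lower A segments with 3162 listed genes, 6.84% of the A genes, and 6 lower C segments with 2594 listed genes, 4.74% of the C genes. Runs above 0.8 in every grouped library formed 4 higher A segments with 1538 listed genes and 0 higher C segments. Where altered segments are left out, these are the lower segments with their homeologs. Each progenitor library was also set against the other libraries of its own group. With each window counted once per library, 0 of 4110 B. rapa and 0 of 4050 B. oleracea values fell below the threshold of -1.5. On A03 the segment ran from 3.47 to 15.66 Mb with 2340 genes, and its part from 4.76 to 14.2 Mb lay between -6.53 and -6.23 in all 6 libraries of the line. On C03 a segment from 0.01 to 3.91 Mb with 794 genes lay between -3.92 and -3.74 in the 5 grouped libraries. Segments on C04 from 52.53 to 53.71 Mb, on C08 from 39.39 to 41.73 Mb and on C09 up to 1.62 Mb lay between -5.54 and -5.23, between -3.34 and -2.28, and between -3.27 and -3.03. A shorter segment on C06 from 38.72 to 39.82 Mb lay between -1.86 and -0.49. Only mock replicate 1 lay below -1.5 there, and the other grouped libraries lay between -1.07 and -0.49. Without mock replicate 1 the scan gave 7 segments with 5543 genes, against 8 with 5756.

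The homeologs of these segments were above the progenitor level. Homeologs of the A03 segment, 444 of 454 of them on C03, lay between 0.71 and 0.79. Homeologs of the C03 segment, 148 of 152 of them on A03, lay between 0.96 and 1.27. For the C04, C08 and C09 segments the homeologs, mainly on A04, A09 and A09, lay between 0.99 and 1.24, between 0.92 and 1.15, and between 0.89 and 1.07. Homeologs of the A01, C01 and C06 segments lay between 0.57 and 0.83, between 0.41 and 0.73, and between 0.43 and 0.77.

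**Figure D5:**
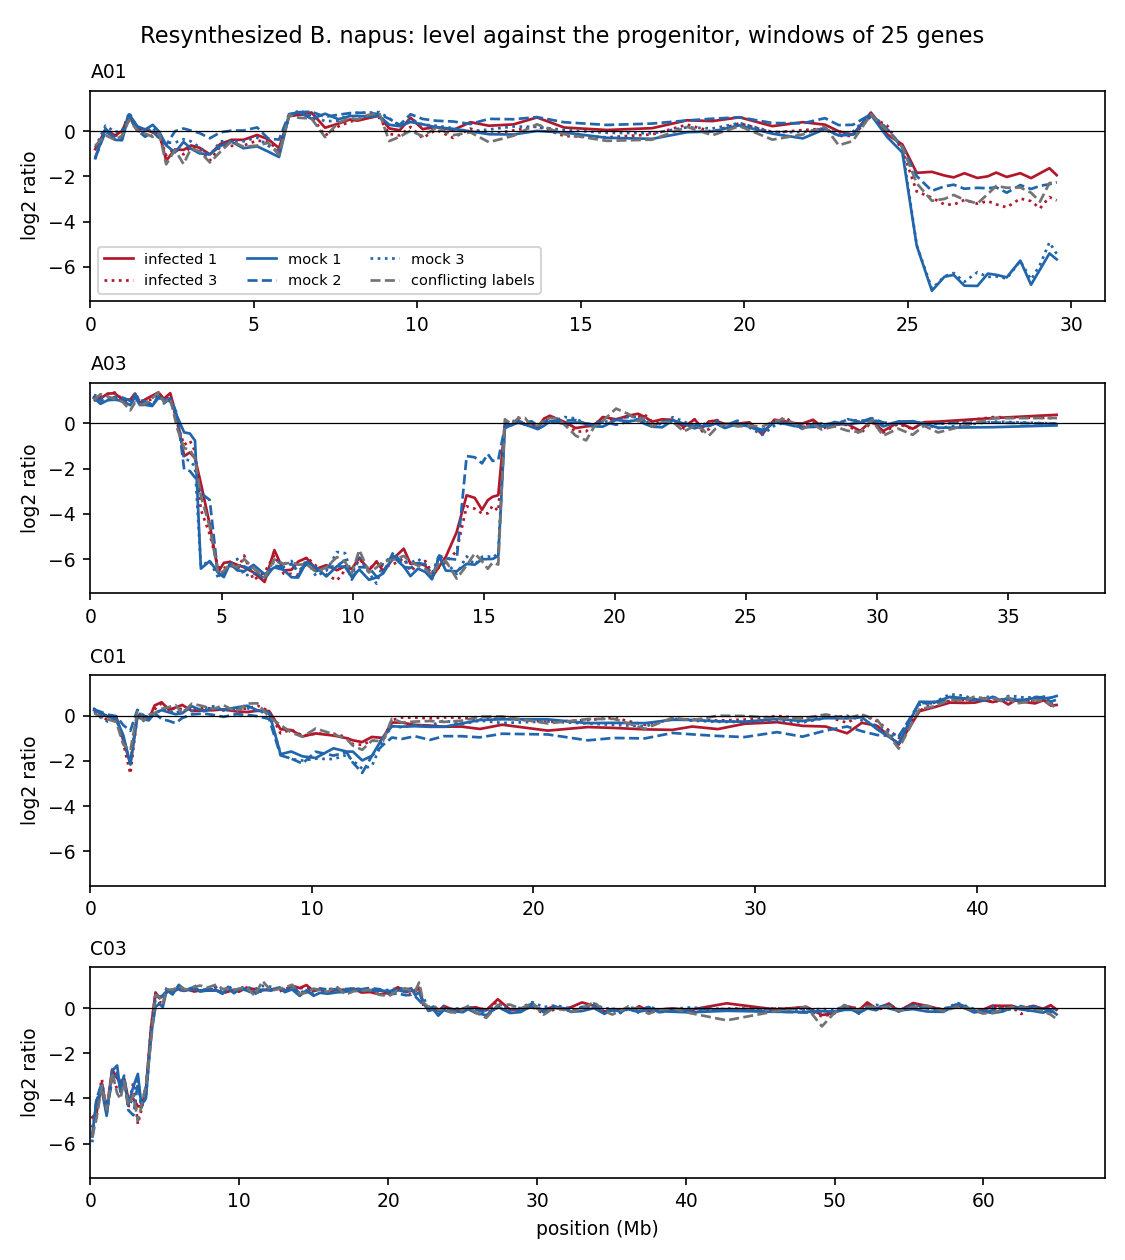
Log2 ratio of each resynthesized B. napus library to its progenitor (vertical axis) in windows of 25 genes along A01, A03, C01 and C03 (horizontal axis, Mb); line colour gives the group and line style the replicate. The libraries separate on A01 beyond 25.04 Mb, where mock replicates 1 and 3 lie near -6.32 and -6.28.

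Several segments differed between libraries of the same line. On A01 from 25.04 to 29.59 Mb, with 822 genes, mock replicates 1, 2 and 3 lay at -6.32, -2.46 and -6.28, and infected replicates 1 and 3 at -1.91 and -3.1. Among the grouped libraries the end of the A03 segment, from 14.2 to 15.66 Mb, differed in a like way. It lay at -6.01, -1.56 and -5.89 in the mock replicates and -3.27 and -3.82 in the infected ones. The library in no group broke this likeness, at -2.7 on A01 and -6.2 at the end of A03. On C01 from 8.37 to 12.84 Mb, with 644 genes, the mock replicates lay at -1.69, -1.94 and -1.92 and both infected replicates at -0.91. The 5 grouped libraries spanned 1.38 in the C06 segment and 1.06 in the C08 segment, against 1.02 on C01. The fold changes of genes there carry these differences. Of the 432 tested genes of the A01 segment, the median log2 fold change was 1.44 in resynthesized B. napus, against 0.07 in B. rapa. For the C01 segment the medians were 0.71 and 0.12 in B. oleracea. Without all lower segments of the line and their homeologs the interaction counts were 6185 for A genes and 1762 for C genes.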

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

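All tests of explanations in this part were chosen after the results were seen. The first 2 results stand here because a response differed between genotypes. B. rapa and the A genes of resynthesized B. napus had a different response in 6040 genes, and B. oleracea and the C genes in 2111. The next 2 stand here because a signal appeared in counts that the comparisons do not use. The genes listed only in the pan-genome set of natural B. napus held 1.5% to 1.58% of counts in infected libraries and 1.17% to 1.22% in mock libraries, and 1422 of the 3042 tested were called, 46.7% against 64.7% of the other genes. In the library with conflicting labels, the median log2 CPM of the genes that rose was 3.41, against 3.4 and 3.45 in the infected and 1.59 to 1.66 in the mock libraries of its line. For the genes that fell it was 0.71, against 0.6 and 0.75 in the infected and 2.21 to 2.31 in the mock libraries.

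The smaller changes in B. rapa than in the A genes of resynthesized B. napus were weighed first. Lower depth is argued against, since B. rapa libraries held 1.38 times as many counts on these genes. A single weak infected library is argued against as well: the slope on the natural B. napus response was at most 0.47 in the 3 infected B. rapa libraries and at least 0.563 in the 2 infected resynthesized libraries. Wholly unaffected tissue in the infected samples would need a share of 43.3% to explain the rises, yet 44.6% of the genes that fell in B. rapa lay below that share of their mock level, and 1228 lay below 21.7% in each infected library. Tissue at an earlier stage of infection and a genetic difference between B. rapa and the line stay open and were not tested.

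The long lower segments of resynthesized B. napus were weighed second. If reads shared with the other copy were lost, the homeologs would lie at or under 0, but the lowest value of any segment in a grouped library was 0.41, and 0.38 in the library in no group. If the sequence of the line's parents differed from the sequenced progenitors and those reads went uncounted, only the segment would lose reads. The median of the homeologs over the segments was 0.89, which argues against that. Because the line was counted on joined gene sets, reads of a differing segment could also be counted on its homeologs and raise them. The test cannot exclude that case. Copies replaced by those of the other subgenome is a candidate explanation: the homeologs of all 6 segments that lie below -1.5 in every grouped library were between 0.5 and 1.5. This is a hypothesis found and tested on the same data, and the genomes of the plants were not analysed here.

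The differences between libraries of that line were weighed last. On A01 the 3 mock libraries span 3.86 on the log2 scale, and mock leaves carried no fungus plug, so infection alone does not explain it. The first bound for this test, 3 times the widest window outside the segments, was not exceeded, because 1 window at the start of A05 spans 4.64, again with mock replicates 1 and 3 lowest. The bound was then changed, after that was seen, to 3 times the 99th percentile of those windows, which is 0.74. B. rapa RNA in some libraries is argued against by the A03 segment, at most -5.65 where A01 is above -4. On C01 the infected libraries lie 0.94 above the mock libraries with little spread within groups, so infection and a difference between plants cannot be told apart there.

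Other splits of the 6 libraries are too few (10 per comparison) for a share under 0.05, with 1 of 10 splits reaching the real count in each. The real counts of called genes were 39554 in natural B. napus, 16497 in B. rapa and 20938 in B. oleracea, and the real count of changed homeolog ratios in natural B. napus was 2384. The highest count of the other splits was 0 in all 4. Each other split mixes infected and mock libraries on both sides, so the response itself widens the spread within its groups. Their low counts therefore lend no weight to the real ones. At an unadjusted p under 0.05, the other splits gave at most 625, 542 and 165 genes with edgeR and 224 pairs with limma.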

How the results depend on the processing

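The segment scan, the leaving out of its segments, and the fold threshold of the ratio were chosen after the data were seen. The counts of called genes stayed within 1.5 times in natural B. napus and B. oleracea under all alternatives run (29103 to 41341, and 14199 to 22745). In B. rapa the exception was the fold threshold, at 9416, and in resynthesized B. napus the reading of the conflicting labels as mock, at 0 with edgeR (10116 at an unadjusted p under 0.05, 4718 with DESeq2). Libraries left out in turn gave 35309 to 39014 in natural B. napus, 26251 to 35788 in resynthesized B. napus, 13317 to 16784 in B. rapa and 17907 to 22599 in B. oleracea. The A share kept its sign except in natural B. napus without the 100 highest genes, at 0.151. The called share difference stayed past the threshold in natural B. napus (2.13 to 4.96). The same difference in resynthesized B. napus did not pass the test at first; it was 1.82 without the altered segments, 1.21 at 2-fold or more, 2.47 without a filter, 0.947 matched on mean counts and -0.669 with each subgenome normalized on its own, and 0.0692 to 1.69 with a library left out. With the conflicting library as mock, 74 A and 38 C genes had a different response and 0 homeolog pairs changed (limma, 1093 unadjusted), and the overlap was 0. As infected, 7962 A genes and 4033 C genes differed, 3602 pairs changed, and the overlap was 27890. With a replicate block these were 3925 A genes, 518 C genes and 1618 pairs (786 toward A and 832 toward C). With that block no other count moved by over 1.5 times. Same-numbered libraries had an r of -0.212 to 0.153 and were not taken as paired. In natural B. napus, however, genes at the start of C03 kept the same order of replicate numbers in both groups, as described further on. Libraries left out gave 2220 to 6674 A genes, 422 to 4390 C genes and 242 to 2460 pairs. Fold thresholds gave 1029 pairs in natural and 1425 in resynthesized B. napus, and an overlap of 16830. For each of these changes the cause was not tested. The conflicting library had an r across genes of 0.995 and 0.996 with the infected libraries of its line. Its r with the mock libraries was 0.86 to 0.865, so the mock reading puts a library with infected-like counts in the mock group. The segment scan gave 5076 to 6990 genes in 5 to 9 segments, against 5756 genes in 8. Of 236 values of the 18 named genes, 232 kept their call and direction; the other 4 lost the call with the conflicting library as mock. With a library left out, the log2 fold changes moved furthest for BraA04g028260.3C (10.16 to 13.3), Bo4g031180.1 (12.72 to 15.98) and Bo9g022280.1 (-9.07 to -6.6). The gene lists, with their estimated correlation and replicate block alternatives, were not run. Of simulated 2-fold changes 0% to 48.5% were recovered, in simulations where far fewer genes changed than in the real data.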

Other observations

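The tests and searches in this part were chosen after the data were seen. A row of 10 neighbouring genes on C02 from 4.62 to 4.63 Mb fell together in B. oleracea, with a median log2 fold change of -6.67. All 10 were called, and their summed level went from 91.5 ± 18 to 0.784 ± 0.72 CPM (SD, n = 3). Of these genes, 9 have a single exon, and their coding lengths are 198 to 300 bp. The same row fell in resynthesized B. napus, with a median of -6.22 and 10 of 10 called. Neighbours on C03 from 4.36 to 4.39 Mb had medians of -5.64 in B. oleracea, with 6 of 10 fallen and 3 risen, and -6.65 in resynthesized B. napus, with 6 fallen and 2 risen, while the summed level went from 490 ± 25 to 380 ± 49 and from 505 ± 81 to 417 ± 56. Windows drawn from shuffled gene orders did not go below -3.29 in B. oleracea and -3.92 in resynthesized B. napus in 100 draws, and 2 and 6 real windows did. On A02 from 3.5 to 3.53 Mb the median was -7.02 in resynthesized B. napus and -2.81 in B. rapa, although 2 genes of the row rose and the summed level in resynthesized B. napus went up, from 34.3 ± 10 to 78.4 ± 5.3 CPM (n = 3 and 2). Among rises, a row on C01 from 10.44 to 10.53 Mb in B. oleracea had a median of 4.17, above the highest shuffled window of 3.45, and its level went from 14.6 ± 3.2 to 332.0 ± 56 CPM. That row lies within the C01 segment that differs between libraries of resynthesized B. napus, where 9 of its genes had a median of 7.01. In windows set along that line's own tested genes, 0 lay above the highest shuffled window of 4.36. The 1 window above in natural B. napus, on C01 from 10.04 to 10.09 Mb, had a median of 3.73 against 3.53, with 6 genes risen and 2 fallen.

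Genes with few exons had larger fold changes than genes with many; their mean counts were not compared. The median absolute log2 fold change for genes with 1 exon and with 10 or more exons was 1.37 and 0.795 in natural B. napus, 1.28 and 0.736 in resynthesized B. napus, 0.899 and 0.501 in B. rapa, and 1.21 and 0.761 in B. oleracea.

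In natural B. napus, 100 measured genes on C03 from 0.01 to 2.68 Mb were lower in replicate 2 of both groups, at 0.642 times the group mean in mock and 0.499 times in infected leaves. Replicates 1 and 3 were at 1.1 and 1.49 times in mock and 1.26 and 1.65 times in infected leaves, so the replicate numbers had the same order in both groups here. Their 39 measured homeologs on A03 were at 1.09 and 1.12 times. The windows of A01 outside the segments of resynthesized B. napus had a median log2 ratio to B. rapa of 0.33 in mock replicate 2 and between -0.13 and 0.09 in the other grouped libraries, the widest range among the chromosomes.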
